A study of Mus musculus with 2 samples.

How the data were processed

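Single-cell RNA libraries had been made from the stromal fraction of mouse perivascular adipose tissue, the fat around the aorta. There were 2 libraries, 1 from young and 1 from old wild-type mice. Per the labels' protocols, minced fat was kept for 45 min in collagenase (0.2%, 37 °C), passed through 70 μm strainers, cleared of red blood cells by lysis and kept in 1% bovine serum albumin. Libraries were prepared with the 10x Genomics Chromium 3′ chemistry, version 2, per the labels' protocols. The ages of the mice, the number of mice behind each library, their sex, the part of the aorta and any time in culture are not given in the sources used here.

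The values deposited by the authors are unnormalized counts of unique molecular identifiers (UMIs) per gene and cell barcode. Per the file headers they were written by Cell Ranger 3.0.1, and per the submitters' processing notes the genome build was mm10. The annotation release and the rule by which barcodes were kept are not given in the sources used here. The young library held 13104 barcodes with 130398999 UMIs in total and a median of 9044.5 per barcode, and the old library 14636 barcodes with 147166475 UMIs and a median of 9108. The lowest total of a barcode was 501 UMIs in the young and 503 in the old library. Genes were taken by their Ensembl identifiers, of which 30934 of 31053 were found in GENCODE vM21 on GRCm38, the build also called mm10. All coordinates below are 1-based and come from that annotation.

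Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left 12755 young and 13711 old cells. Barcodes over the mitochondrial limit made up 1.83% of the young and 5.78% of the old library. Scrublet, run per library in scanpy 1.11.5, marked 0 cells with its automatic threshold in either library, so that threshold did not work. The planned rule was used instead: the cells with the highest doublet scores were removed, 0.8% per 1000 cells left by the filter. This took out 1302 young cells (10.2%) and 1504 old cells (11.0%) and left 11453 and 12207 cells. How many doublets remain is not known. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen per library and combined, and both libraries were clustered together without integration, with 30 components, 15 neighbours and the Leiden algorithm at resolution 1 (igraph 0.11.9). Clusters were named from 25 marker lists fixed before the data were examined. For names other than fibroblastic stromal, a marker counted where at least 25% of the cluster's cells held it at 2-fold or more the CPM of other cells. Such a name needed at least 3 of these markers. The fibroblastic stromal name needed at least 3 fibroblastic markers held by at least 25% of cells, with no fold limit. It was given only where no other name applied and no other list had more genes among the cluster's 10 leading genes. These numerical limits, and the separation of mesenchymal clusters led by contractile, cycling or pericyte markers from the fibroblastic stromal class, were set after the clusters had been seen.

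Cells are not replicates, and with 1 library per age no test across animals exists. UMIs were therefore summed per library and class and given as CPM, that is scaled to the total UMIs of the class, with log2(old/young) and an exact conditional Poisson 95% interval. Shares of cells carry exact Clopper-Pearson 95% intervals. All intervals cover counting error only, no difference has a replicate check, and no p-value is given. A library with 0 UMIs of a gene was set to 3 for ratios, which then depend on that value. For 28 gene lists fixed before the data were examined, the median log2(old/young) of members with at least 20 UMIs was set against 10000 random lists of the same size matched on mean expression, and members at least 1.5-fold higher or lower were counted. The interval of a list's median comes from 1000 Poisson resamplings.

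Named genes followed a rule fixed in advance. In fibroblastic stromal cells these were the 12 genes with the largest and the 12 with the smallest log2(old/young) among genes with at least 200 UMIs, and in other classes with at least 100 cells in both libraries the 5 largest and 5 smallest. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and sex chromosome genes were left out of the ranking, as were genes whose CPM was under 10% of that in another class with at least 50 cells. For each list up to 4 members with the largest absolute ratio and at least 100 UMIs could be named. Tagln, Acta2, Myh11, Ppargc1a, Ucp1, Cdkn2a, Xist and Ddx3y could be named whatever their values. The 10% limit against other classes was not applied to these genes and list members. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs. Lymphocytes, planned as background for these shares, formed no cluster, and Schwann, endothelial and macrophage cells were used. Genes of multigene families such as H2-Q4, H2-Q7 and C130026I21Rik can share reads with near-identical copies, and Gm16685 is annotated as antisense, so their values are uncertain. Some results that these rules select are not reported here.

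The statistics were tested on simulated Poisson counts with 200 changed genes per class. The intervals assume the same model, so coverage near 95% was built in, and variation between cells, animals or libraries was not simulated. In fibroblastic stromal cells, coverage of changed genes ran from 88% at 2-fold to 96% at 16-fold. In the simulated fibroblastic stromal comparison, run on 11014 genes, the interval lay on the true side of 0 for 96% of genes changed 1.5-fold and for 100% at 2-fold, 4-fold and 16-fold, and it covered the true value of 94.9% of unchanged genes. On 3199 genes of the mesothelial comparison it lay on the true side for 82% at 1.5-fold, and on 1343 genes of the Schwann comparison for 92%. Alternatives covered the cell filter, doublet removal, clustering resolution, clustering each library on its own, median-of-ratios size factors, equal weights per cell or subcluster, the count minimums, the free RNA rule and the thinning depth. The filter, doublet and resolution alternatives each cluster the cells anew, so they also change which cells make up a class. A comparison over all mesenchymal clusters together, and the shares of the mesenchymal groups under each setting, were added after the data had been seen.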

Results

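Perivascular adipose tissue surrounds the aorta and holds stromal cells in its adventitial border. The series compared such cells from young and old mice, under a title that ties stromal cells with a history of SM22α (the product of Tagln) to abdominal aortic aneurysm. After filtering, 11453 cells of the young library and 12207 of the old library were compared, with medians of 8916 and 9222 UMIs per cell. In fibroblastic stromal cells the Y-linked gene Ddx3y stood at 72.7 CPM in the young and 93.6 CPM in the old library, while Xist, the RNA of the inactive X chromosome, had 4 and 6 UMIs.

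The first comparison asked which cells each library held. Mesenchymal cells, with collagen genes and Pdgfra among their markers, made up most of both libraries, 89.7% of young cells (95% interval 89.1 to 90.2) and 83.3% of old cells (82.7 to 84.0). Blood endothelial cells, which line vessels, were 0.297% of the young (0.206 to 0.415) and 9.32% of the old library (8.81 to 9.85). Mesothelial cells, the covering layer of serous surfaces, were 3.61% of the young (3.28 to 3.97) and 0.975% of the old library (0.808 to 1.17). Schwann cells, the glia of peripheral nerves, were 1.35% (1.15 to 1.58) and 1.25% (1.06 to 1.46).

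Adipocytes were 0.0524% of young and 0.926% of old cells, and macrophages 0.00873% and 0.860%, the young value resting on 1 cell. Striated muscle cells were 0 of 11453 young cells, with an upper bound of 0.0322%, and 0.139% of old cells. Cluster 9, with 5.003% of young and 3.19% of old cells, kept no name because immunoglobulin genes led it, although 5 of its 963 cells were rich in immunoglobulin UMIs. Its name depends on the settings: clusters with the same leading genes S100a6 and Tpm2 were named smooth muscle with the looser cell filter and in the old library on its own, and fibroblastic stromal in the young library on its own. Which cells survive a collagenase digest can set all of these shares.

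**Figure D1:**
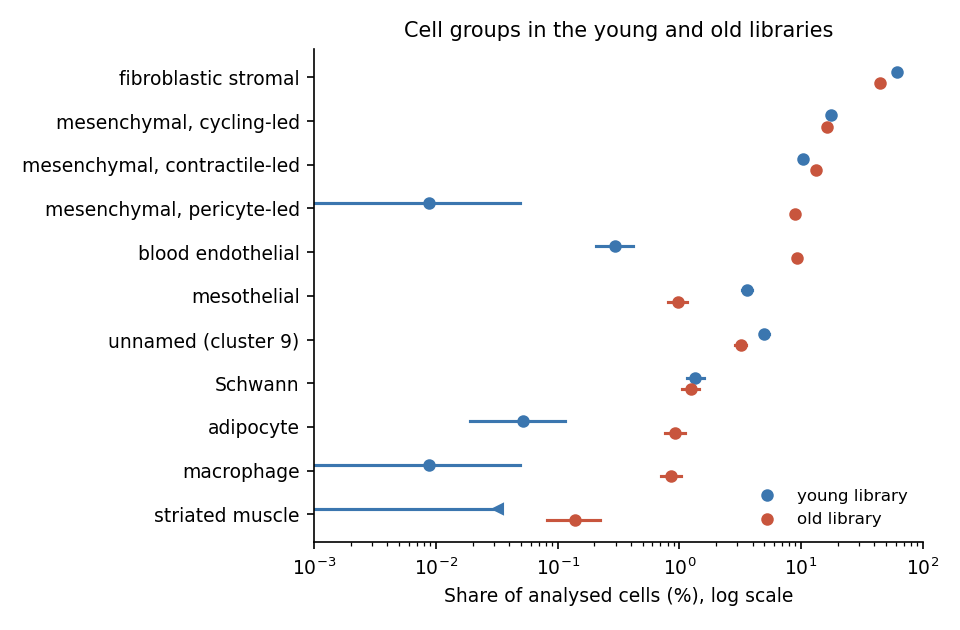
Share of analysed cells in percent (log scale) for each group of clusters in the young library (blue) and the old library (red). Points are shares, horizontal lines are exact 95% binomial intervals cut at the left edge of the axis, and the arrowhead marks the upper bound for 0 cells; blood endothelial cells were 0.297% of the young and 9.32% of the old library.

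Within the mesenchymal cells, the class called fibroblastic stromal was 61.6% of young (60.7 to 62.5) and 44.6% of old cells (43.7 to 45.5). The other mesenchymal clusters, set apart after the data were seen because contractile, cycling or pericyte markers led them, held 28.1% of young and 38.8% of old cells. Clusters led by contractile genes held 10.4% and 13.3%, clusters led by cell cycle genes 17.6% and 16.4%, and the cluster led by pericyte genes 0.00873% and 8.98%. These divisions depend on the settings. The fibroblastic stromal class was 65.8% of young and 63.6% of old cells without doublet removal, 52.0% and 49.7% with the looser cell filter, 56.2% and 51.0% with each library on its own, 78.5% and 65.7% at Leiden resolution 0.5, and 64.5% and 47.3% at resolution 2. Contractile-led or smooth muscle clusters held 3.94% of young and 0.0948% of old cells without doublet removal, the opposite direction, and no pericyte-led cluster formed there, at resolution 0.5 or with the looser filter. Cycling-led clusters held 11.2% and 17.6% at resolution 0.5, again the opposite direction. Almost no mesenchymal cluster was shared. In each of the 15 mesenchymal clusters at least 99.3% of the cells came from 1 library. The class consisted of clusters 0, 2, 3, 6 and 8 in the young library and of clusters 13, 14, 18 and 20 in the old library, and such clusters may stand for a library rather than a cell type.

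Fibroblastic stromal cells of the old library held far more transcripts of secreted inflammatory genes. Cxcl1, a neutrophil-attracting chemokine, stood at 27.5 CPM in the young and 4023 CPM in the old library, 146-fold higher (log2 7.19, interval 7.12 to 7.26). Cxcl5, a related chemokine, was 113-fold higher (28.7 and 3240 CPM). Ccl11, which attracts eosinophils, was 130-fold higher (0.418 and 54.2 CPM), and Saa3, an acute-phase protein gene, 101-fold higher (20.9 and 2124 CPM). Lcn2, which encodes an iron-siderophore-binding protein of innate defence, was 111-fold higher (1.98 and 219 CPM). These values come from 7055 young and 5442 old cells with 64569973 and 50147011 UMIs.

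Pi16, a marker of adventitial progenitor fibroblasts, was 96.1-fold higher (0.914 and 87.8 CPM, log2 6.59, 6.22 to 6.98). Areg, which encodes the growth factor amphiregulin, was 100.4-fold higher and Nppc, the gene of C-type natriuretic peptide, 93.5-fold higher. The log2 ratio of Areg was 6.65 in the class and 5.30 over all mesenchymal clusters. Scarcer genes with large ratios were Gm16685 with 7 and 497 UMIs, Trdc, annotated as the constant segment of the T cell receptor delta chain, with 3 and 238, and C130026I21Rik with 2 and 206 (log2 7.05, 5.18 to 10.11). Cxcl1 (ENSMUSG00000029380) lies on chromosome 5 from 90891241 to 90893115 on the forward strand of GRCm38. Cxcl5 (ENSMUSG00000029371, 90759360 to 90761624) and Areg (ENSMUSG00000029378, 91139599 to 91148432) lie on the same chromosome and strand. Pi16 (ENSMUSG00000024011) lies on chromosome 17 from 29317680 to 29330593.

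Other genes were lower in old stromal cells. Col11a1, a minor fibrillar collagen, stood at 69.5 CPM in the young and 3.69 CPM in the old library, 18.8-fold lower (log2 -4.24, -4.46 to -4.02). Ptn, the gene of the heparin-binding growth factor pleiotrophin, was 12.8-fold lower (50.9 and 3.99 CPM), and Itga8, an integrin subunit gene, 14.7-fold lower. Barx1, a homeobox gene, was 32.3-fold lower, the cytokine-like gene C1qtnf3 36.8-fold lower, and Cav3, the muscle caveolin gene, 30.03-fold lower. Lmo7 was 27.7-fold, Cdh6, a cadherin gene, 22.1-fold, the amino acid transporter gene Slc38a4 12.7-fold and the kinase gene Tnik 10.6-fold lower. Over all mesenchymal clusters log2 ratios were -3.32 for Lmo7 and -2.69 for Slc38a4, against -4.79 and -3.66 in the class. Col11a1 and Ptn were among the leading genes of young cluster 8 (923 cells), Cdh6 of young cluster 2 and Itga8 of young cluster 6. Old cluster 20, which shared Tbx20 and Tcf21 with cluster 8 among its leading genes, had 216 cells. Whether the mix of such clusters accounts for the lower values was not tested.

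Alkal1, the gene of a ligand of the receptors ALK and LTK, had 474 UMIs in the young and 1 in the old library (log2 -8.52, -13.83 to -6.04). Its log2 ratio was -6.16 over all mesenchymal clusters. With the young library clustered on its own, C1qtnf3, Itga8 and Alkal1 were among the leading genes of 179 cells named smooth muscle. Whether such cells account for the lower values in the class was not tested. Mgl2, a lectin gene best known from macrophages and dendritic cells, had 215 and 0 UMIs. It was 55.7-fold lower with the 0 set to 3 (log2 -5.80, upper limit of the interval -5.49). Col11a1 (ENSMUSG00000027966) lies on chromosome 3 from 114030540 to 114220718, and Ptn (ENSMUSG00000029838) on chromosome 6 from 36714929 to 36810220 on the reverse strand.

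Immune signalling lists were higher as groups. Of 23 measured chemokines and cytokines, 22 were at least 1.5-fold higher in the old library and 0 lower, with a median log2(old/young) of 3.91 (3.50 to 4.14), above all 10000 matched random lists. The neutrophil chemokine gene Cxcl2 had 9 and 7862 UMIs (log2 10.13), and Il11, a cytokine of fibroblasts, was 36.3-fold higher. Cxcl2 was left out of the ranking of named genes, because its CPM was under 10% of that in another class. Of 14 complement genes 11 were higher and 0 lower (median 2.30, 2.21 to 2.40), among them C3, the central component, 7.22-fold, Cfb 17.3-fold and Cfd, the adipsin gene, 33.6-fold. All 14 measured genes of class I antigen presentation, which shows peptides to CD8 T cells, were higher (median 1.203, 1.13 to 1.30), with Psmb8 of the immunoproteasome 3.29-fold and H2-K1 2.76-fold. The median of these lists lay at percentile 100 of the random lists, against a median of 0.15 over all genes of the class (0.12 over all mesenchymal clusters).

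Other immune lists also had medians above 0. Class II antigen presentation had 7 of 8 measured members higher (median 1.53), with the invariant chain gene Cd74 10.6-fold higher at 12 and 99 UMIs. Of 29 interferon response genes 20 were higher and 1 lower (median 0.93), Gbp2, a guanylate-binding protein gene, 5.90-fold higher and Ifit2 2.90-fold lower. The list for lipid-associated and inflammatory macrophages had 9 of 15 members higher and 1 lower (median 1.81), which include Cxcl2 again, the osteopontin gene Spp1 (5.14-fold) and Lgals3 (4.42-fold). Resident macrophage genes had 3 of 7 higher and 1 lower (median 0.57, percentile 91.2), Pf4 21.9-fold at 39 and 663 UMIs. Endothelial activation genes had 12 of 17 higher and 2 lower (median 1.64), the P-selectin gene Selp 39.1-fold at 29 and 880 UMIs.

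Markers of other cell types moved with these lists inside the stromal class. Blood endothelial markers had a median log2(old/young) of 3.87, adipocyte markers 2.66, group 2 innate lymphoid markers 2.51, macrophage markers 2.33, plasma cell markers 1.82, platelet markers 1.54, lymphatic endothelial markers 1.29, pericyte markers 0.89, fibroblastic markers 0.46 and Schwann markers 0.06. Monocyte markers stood at -0.33, neutrophil markers at -1.07, striated muscle markers at -1.13, proliferating markers at -1.24, smooth muscle markers at -1.37 and mesothelial markers at -1.74. For dendritic, mast, basophil, T, natural killer, B, erythroid, epithelial and neural or chromaffin lists at most 2 markers were measured. The endothelial gene Cdh5 was at 0.139 and 4.69 CPM in stromal cells and at 393 CPM in old endothelial cells. Cfd and Adipoq were among the leading genes of the adipocyte cluster, with 6 young and 113 old cells. Selp was among those of endothelial cluster 11 (32 and 1064 cells), and Pf4 led the macrophage cluster (1 and 105 cells). Whether free RNA from these cells added to the stromal values of these genes was not tested.

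**Figure D2:**
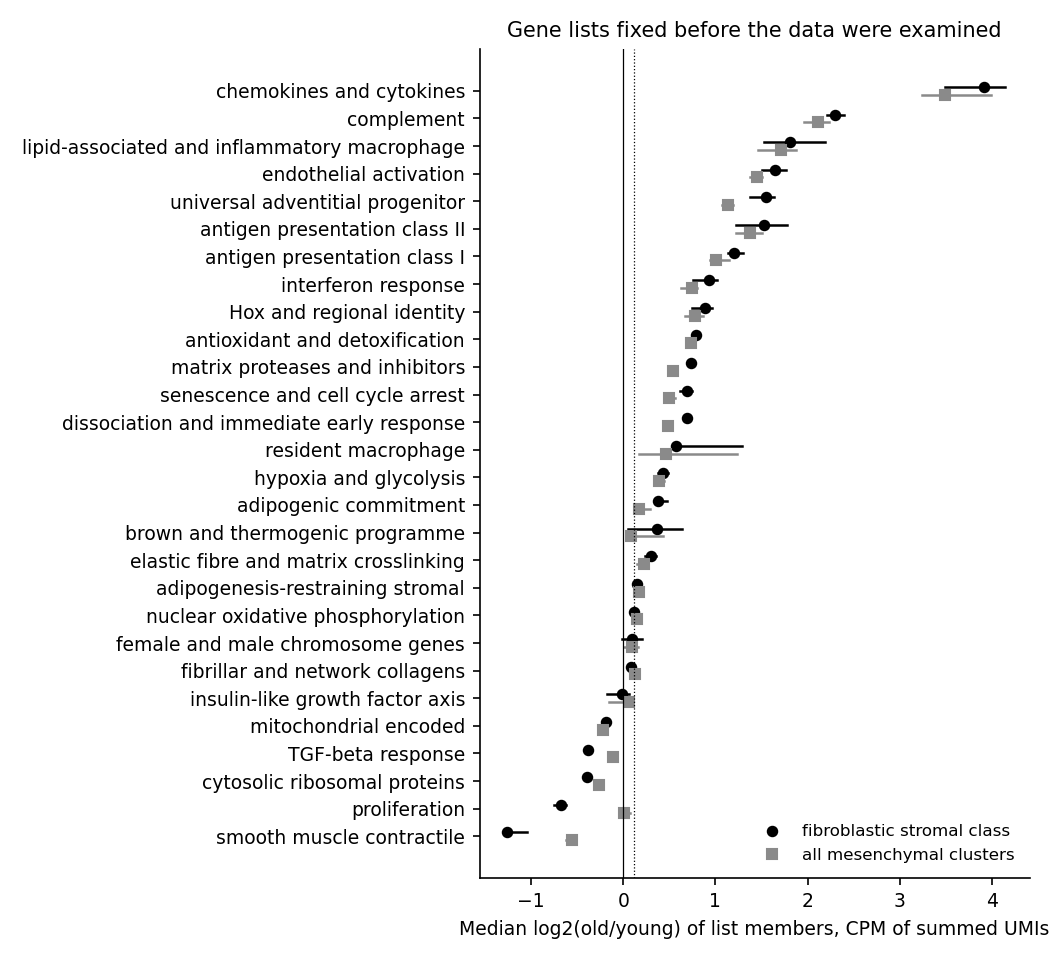
Median log2(old/young) of the members of each list in the fibroblastic stromal class (black circles) and in all mesenchymal clusters (grey squares); horizontal lines are 95% intervals from Poisson resampling, the solid line marks 0 and the dotted line the typical median of matched random lists. Chemokines and cytokines (3.91 and 3.50) stand highest and smooth muscle contractile genes (-1.26 and -0.55) lowest; collagens and nuclear oxidative phosphorylation genes lie above 0 here and below 0 with median-of-ratios size factors, collagens also with each library clustered on its own, and the proliferation list changes sign between the 2 groupings (-0.68 and 0.01).

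Progenitor and adipogenic programmes differed in degree. Of 20 universal adventitial progenitor genes 13 were higher and 2 lower in the old library (median 1.55, 1.38 to 1.64, percentile 100). Procr, the endothelial protein C receptor gene, was 16.1-fold, Igfbp5 23.7-fold and Ackr3, a chemokine scavenger receptor gene, 9.36-fold higher. Adipogenic commitment genes had 11 of 24 higher and 3 lower (median 0.38, percentile 96.3; over all mesenchymal clusters 0.17, percentile 66.4), with the adiponectin gene Adipoq at 16 and 164 UMIs and Klf5, an early adipogenic factor, 7.56-fold lower. In the brown and thermogenic programme 6 of 15 were higher and 4 lower (median 0.36, percentile 87.1; over all mesenchymal clusters 0.08, percentile 40.5). Dio2, which activates thyroid hormone, was 22.1-fold higher (2.23 and 49.2 CPM), Pparg 2.94-fold higher, and Ppargc1a, a regulator of mitochondrial genes, had 63 and 102 UMIs. Ucp1, the uncoupling protein of brown fat, had 1 and 11 UMIs (log2 3.82, 1.04 to 9.25). It was at 31.1 CPM in old adipocytes against 0.219 CPM in old stromal cells, and free RNA from adipocytes was not tested. Genes that restrain adipogenesis had 6 of 17 higher and 4 lower (median 0.15), the chemerin gene Rarres2 9.57-fold higher and F3, the tissue factor gene, 3.73-fold lower.

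The lists for the extracellular matrix were mixed. Collagens had 6 of 17 higher and 2 lower, and their median of 0.08 became -0.07 with median-of-ratios size factors and -0.05 with each library clustered on its own. Col6a1 was 2.80-fold and Col14a1 3.37-fold higher. The summed collagen level over all mesenchymal clusters was lower in the old library (8622 and 7269 CPM). Elastic fibre and crosslinking genes had 5 of 21 higher and 5 lower, with a median of 0.30 and a mean of -0.15. Eln, which encodes elastin, was 7.18-fold lower (61.3 and 8.54 CPM) and Fbn2, a fibrillin gene, 4.77-fold lower. Eln was among the leading genes of young clusters 2 and 6 of the class. With the old library on its own, Eln led a pericyte-led cluster of 747 cells, a kind set apart from the class. The ratio of Eln may therefore depend on that division. Matrix proteases and their inhibitors had 13 of 25 higher and 3 lower (median 0.73, percentile 99.99), the collagenase gene Mmp13 7.83-fold and Adamts4 4.39-fold higher.

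Stress and arrest lists had medians above 0, with part of their members under 1.5-fold. Of 25 dissociation and immediate early genes 14 were higher and 0 lower (median 0.69), Atf3 11.6-fold and Nr4a1 4.44-fold. Senescence and arrest genes had 12 of 20 higher and 3 lower (median 0.69), with the stress cytokine gene Gdf15 16.3-fold and Cdkn2a, the p16 locus, 1.64-fold higher (18.6 and 30.5 CPM). Antioxidant genes had 12 of 20 higher and 1 lower (median 0.79), the mitochondrial superoxide dismutase gene Sod2 10.4-fold. Hypoxia and glycolysis genes had 7 of 18 higher and 0 lower (median 0.44), Vegfa 3.42-fold. The insulin-like growth factor axis had 4 of 18 genes higher and 6 lower (median -0.02, over all mesenchymal clusters 0.07), with the imprinted gene Peg3 6.05-fold lower. Mitochondrially encoded genes had 1 of 13 lower (median -0.19), cytosolic ribosomal protein genes 4 of 26 (median -0.40, over all mesenchymal clusters -0.26) and sex chromosome genes 0 of 4 (median 0.10), with none higher. Nuclear oxidative phosphorylation genes had 0 of 23 at least 1.5-fold apart and a median of 0.11, which became -0.04 with median-of-ratios size factors. The proliferation list was at -0.68 with 13 of 22 genes lower, in a class from which cycling clusters had been set apart, and at 0.01 over all mesenchymal clusters.

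Hox genes, which mark position along the body axis, differed by paralogue group. Of 22 measured members of the Hox and regional list 14 were higher and 0 lower in old stromal cells (median 0.88, percentile 100). Hoxc9 stood at 1.46 and 8.85 CPM, 6.08-fold higher, Hoxc8 was 4.10-fold and Hoxa7 3.93-fold higher. Over all Hox genes with at least 20 UMIs, the median log2(old/young) was -0.22 for the 7 genes of paralogue groups 2 to 4, 1.36 for the 8 genes of groups 5 to 7 and 2.04 for the 7 genes of groups 8 to 10. Hoxc13, outside the list, was lower (-0.90).

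**Figure D3:**
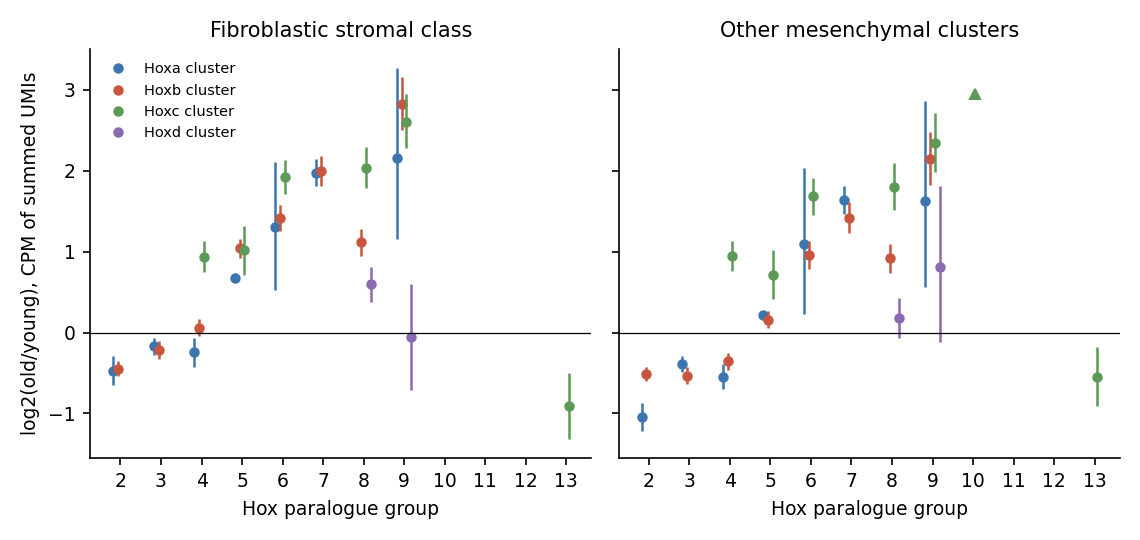
Log2(old/young) of Hox genes with at least 20 UMIs in paralogue groups 2 to 13 against the paralogue group, in the fibroblastic stromal class (left) and in the other mesenchymal clusters (right), coloured by Hox cluster; vertical lines are exact 95% counting intervals and the triangle is a lower bound for a gene with 0 UMIs in the young library. Medians of groups 2 to 4 lie below 0 in both panels (-0.22 and -0.51) and those of groups 8 to 10 above (2.04 and 1.72), while Hoxc13 lies below 0.

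The next comparison concerned Tagln, the gene of SM22α in the series title, and other contractile genes. In fibroblastic stromal cells Tagln (ENSMUSG00000032085, chromosome 9, 45929619 to 45936058, reverse strand) was at 1095 CPM in the young (1087 to 1103) and 527 CPM in the old library (520.5 to 533), log2 -1.06. It was 1144 and 781 CPM over all mesenchymal clusters (log2 -0.55). Myh11, the smooth muscle myosin heavy chain gene, was at 8.66 and 3.09 CPM, and at 12.8 and 9.01 CPM over all mesenchymal clusters (log2 -0.51). Of its 559 young UMIs 372 came from cluster 6, and the other young clusters of the class together stood at 3.86 CPM. Acta2, smooth muscle actin, was at 1798 and 1140 CPM (log2 -0.66), but at 2003 and 1968 CPM over all mesenchymal clusters, and its log2 ratio in the class was 0.07 in the clustering without doublet removal, where the class also took in 87.7% of the young and 94.0% of the old contractile-led cells and 97.6% of the old pericyte-led cells. Of 17 contractile genes 11 were lower and 2 higher (median -1.26, percentile 0), among them Lmod1 10.0-fold, the desmin gene Des 5.76-fold and Cnn1 4.199-fold. That median was -0.55 over all mesenchymal clusters, -0.51 in the clustering without doublet removal and -0.59 at Leiden resolution 0.5, and in both of the latter the class took in most of the contractile-led cells of both libraries and most of the old pericyte-led cells. Cnn1 stood at 289 CPM in young cluster 6 of the class, and at 296 and 202 CPM in contractile-led clusters 1 (young) and 21 (old) outside it. TGF-beta response genes had 7 of 18 lower and 4 higher (median -0.38), and 6 lower and 5 higher over all mesenchymal clusters (median -0.12). In the class Ctgf was 5.61-fold and Thbs1 3.20-fold lower.

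Thinned to 1000 UMIs, 57.6% of young (56.5 to 58.8) and 33.3% of old fibroblastic stromal cells (32.0 to 34.5) held a Tagln UMI, with 21 and 3 shallower cells left out. The share of stromal cells with a Tagln UMI, old minus young, was -24.4 points, and was -15.9 points in the clustering without doublet removal and -16.2 points over all mesenchymal clusters. Unthinned shares were 94.7% and 84.0%, at median depths of 8257 and 8124.5 UMIs. As background, 16.1% and 28.3% of Schwann cells held a Tagln UMI, at median depths of 6746 and 5134.5. Among blood endothelial cells it was 17.6% of 34 young cells (6.76 to 34.5) and 11.5% of 1135 old cells (9.74 to 13.5). Among old macrophages it was 8.57%. The values differed between clusters of 1 library. Among fibroblastic stromal clusters Tagln ran from 979.7 to 1543 CPM in the young library and from 443 to 810.2 CPM in the old. Clusters led by contractile genes were at 1575 CPM (cluster 1, young) and 1394 CPM (cluster 21, old), and their Acta2 at 2713 and 3614 CPM. A UMI shows a transcript at the time of capture and not a cell's lineage.

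**Figure D4:**
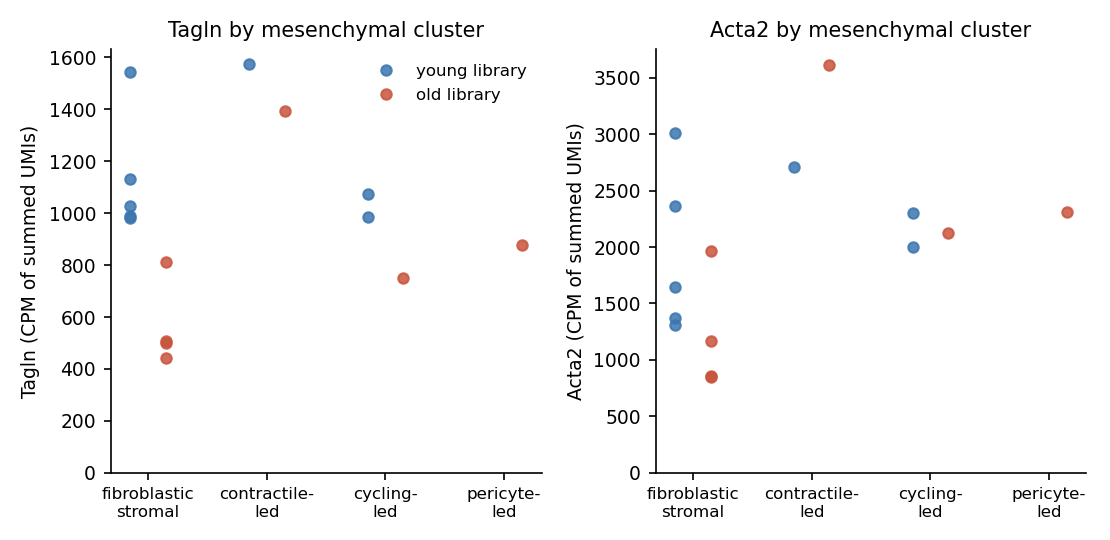
Tagln (left) and Acta2 (right) in CPM of summed UMIs, 1 point per mesenchymal cluster, in the young (blue) and old (red) library, without the unnamed cluster 9. Tagln in fibroblastic stromal clusters lies between 979.7 and 1543 CPM in the young and between 443 and 810.2 CPM in the old library, while Acta2 overlaps and in the class is at 0.07 on the log2 scale in the clustering without doublet removal, which also redraws the class.

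Fibroblastic stromal cells were clustered again to ask whether the differences over the class also stood between its subclusters. This gave 9 subclusters, 6 of the young and 3 of the old library, and 99.9% of cells lay in a subcluster made up mainly of their own library. Chemokine and cytokine genes summed to between 669.6 and 2028 CPM in young and between 13096 and 18606 CPM in old subclusters. Complement genes ran from 51.7 to 231 and from 556 to 1229 CPM, class I antigen presentation from 434 to 670.1 and from 1047 to 1542 CPM, and progenitor genes from 1435 to 2794 and from 3843 to 5139 CPM. Contractile genes overlapped, from 2809 to 10258 CPM in young and from 4681 to 6640.0 CPM in old subclusters, as did thermogenic genes. Tagln itself overlapped at this level, from 206 to 1535 CPM and from 431 to 764 CPM, through the young subcluster 5 of 41 cells, while the other young subclusters stood at 954 CPM or more. Stress and immunoglobulin genes led some old subclusters, Atf3 in subcluster 6 and Igkc in subcluster 8. With 14 subclusters at resolution 1, complement, class I and progenitor sums of young and old subclusters overlapped as well, through a young subcluster of 29 cells.

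The last comparison took the other classes with at least 100 cells in both libraries, Schwann and mesothelial cells, each a single cluster holding both libraries. Chemokines and cytokines were higher in old Schwann cells (median 2.93, 2.61 to 3.21, 8 of 11 higher and 2 lower) and in old mesothelial cells (median 1.51, 1.24 to 2.002, 11 of 16 higher and 1 lower). Cxcl1 was at 2.72 and 488 CPM in Schwann cells and at 52.4 and 1933 CPM in mesothelial cells. The summed chemokine and cytokine level was 2436.5 CPM in old Schwann cells and 15356 CPM in old fibroblastic stromal cells. The adventitial marker Pi16 stood at 12.3 CPM in old Schwann cells and 87.8 CPM in old fibroblastic stromal cells. Free RNA from stromal cells as a source of chemokine UMIs in Schwann and mesothelial cells was not tested. In 155 young and 152 old Schwann cells, Igfbp5, a binding protein of insulin-like growth factors, was 32.0-fold higher (57.1 and 1830.2 CPM), Phactr1 25.1-fold and the immediate early gene Nr4a1 13.7-fold higher. Lower were Angptl4, an inhibitor of lipoprotein lipase (6.45-fold), Ubash3b (4.57-fold), Adamts1 (3.76-fold), the myelin basic protein gene Mbp (3.70-fold) and Rgs16 (3.68-fold).

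In 414 young and 119 old mesothelial cells Cxcl5 was 66.8-fold, Il6 46.0-fold and Ccl7, a monocyte chemokine gene, 13.8-fold higher. Lower were Edn1, the endothelin gene (7.05-fold), Lbh (4.44-fold), Cdkn2a (4.36-fold), Hacd4 (3.995-fold) and Gyg, the glycogenin gene (3.78-fold). Complement genes had 8 of 9 higher in mesothelial cells (median 1.32). Interferon response genes had a median of -1.56 in Schwann cells, where 9 of 29 were measured (0 higher, 6 lower). In mesothelial cells their median was -0.28 with an interval across 0 (-0.58 to 0.14; 6 of 25 higher, 10 lower), while their summed level was higher in the old library (1806 and 2138.5 CPM). Differences between classes were not tested. Immediate early genes had medians of 0.69 and 0.74. Contractile genes had medians of 0.42 in Schwann and -0.62 in mesothelial cells. AY036118, a noncoding gene on chromosome 17, was among the highest ratios in both classes, 14.1-fold in Schwann and 10.9-fold in mesothelial cells, and was 12.2-fold higher in stromal cells.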

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

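The search of 45 genes for opposite directions and the count of immunoglobulin-rich barcodes were both chosen after the comparisons had been seen, and no difference between classes was tested, since each class has 1 library per age. Several genes moved one way in stromal cells and the other way in a second class, each with a counting interval on its own side of 0. Col11a1 was higher in old Schwann cells (log2 1.65, 1.22 to 2.09) and lower in old stromal cells (-4.24). Ptn behaved likewise, at 2.88 in Schwann cells (35.4 and 260.1 CPM) and -3.67 in stromal cells. In the stromal class, Col11a1 and Ptn were among the leading genes of young cluster 8. Tagln was at 0.70 in Schwann and -1.06 in stromal cells, and Acta2 at 1.26 and -0.66. Schwann cells also served as background for Tagln UMIs, and free RNA as a source of both genes there was not tested. Acta2 stood at 201 and 483 CPM in Schwann cells, against 3444 and 5362 CPM in the unnamed cluster 9. The opposition of Acta2 does not hold in every setting, since its stromal value was 0.07 in the clustering without doublet removal. Over all mesenchymal clusters its value was near 0, at -0.025 (-0.034 to -0.016). Rgs16, a regulator of G protein signalling, was at -1.88 in Schwann and 1.16 in stromal cells. Cdkn2a was at -2.13 in mesothelial cells (157 and 35.9 CPM) and 0.72 in stromal cells (18.6 and 30.5 CPM).

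Barcodes with at least 10% immunoglobulin UMIs, as plasma cells give, stood out outside the comparisons. They were 9 of 14636 barcodes in the old library (0.0615%, 0.0281 to 0.117) and 0 of 13104 in the young, with an upper bound of 0.0281%. Of the 9, with between 17.7% and 76.8% immunoglobulin UMIs, 5 lay in the unnamed cluster, 1 in the stromal class and 3 had been removed by the filters.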

How the results depend on the processing

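The grouping of all mesenchymal clusters together was chosen after the data had been seen; the other alternatives were planned. Of 1066 alternative values of 138 results, 810 stayed within counting error, 251 moved beyond it and 5 changed sign. The pooled count rests largely on Schwann and mesothelial cells, where 482 of 497 values stayed and 15 moved. Stromal list medians were less stable: of 280 values 136 stayed, 140 moved and 4 changed sign. A change of sign was counted only where the interval of the first value lay on 1 side of 0, so lists near 0, such as the insulin-like growth factor axis, are outside that count. None of the 192 values of the 24 named stromal genes and none of the 497 in Schwann and mesothelial cells was counted so. The 24 genes had been picked for the most extreme ratios in these same data, so a change of sign was unlikely from the outset. Schwann and mesothelial clusters kept nearly the same number of cells at each clustering resolution, which left little room for change there. The cause of the shifts below was not tested, except where the alternative itself adds cells, changes the scale or drops genes. With median-of-ratios size factors, which shift all genes by a common amount, medians became -0.0655 for collagens and -0.0378 for nuclear oxidative phosphorylation (both from above 0), -1.41 for contractile, 2.15 for complement and 1.05 for class I genes. Weighting cells equally gave progenitor 1.34 and contractile -1.29. Over all mesenchymal clusters, medians were progenitor 1.14, contractile -0.55, chemokine 3.50, complement 2.11, class I 1.00 and proliferation 0.00923 (from below 0), and the share of stromal cells with a Tagln UMI, old minus young, was -16.2 points instead of -24.4. Equal weights per subcluster gave progenitor 1.66, contractile -0.91 and complement 2.64. Without thinning the Tagln difference was -10.7 points. The looser cell filter gave a share of all mesenchymal cells, old minus young, of -7.74 points, progenitor 1.23, complement 2.07 and Tagln -21.1 points. Clustered without doublet removal, which also put 87.7% of the young and 94.0% of the old contractile-led cells into the class, progenitor was 1.05, contractile -0.51, complement 2.04, class I 1.07, Schwann chemokine 2.56, Acta2 0.0720 (from below 0) and Tagln -15.9 points. Leiden resolution 0.5, which put in 99.7% and 94.8%, gave progenitor 1.19, contractile -0.59, complement 2.09 and Tagln -17.9 points, and resolution 2 progenitor 1.37 and Tagln -22.4 points. With each library clustered on its own, the mesenchymal share difference was -9.08 points, with progenitor 1.11, collagens -0.0490 (from above 0), contractile -0.91, complement 2.17, class I 1.05, Schwann chemokine 2.20 and Tagln -22.6 points. With at least 1000 UMIs required, 10 of the 24 named genes were still named, since scarcer genes drop out. A median log2 ratio within each subcluster was not run, because almost every subcluster held 1 library. No paired analysis was possible because each age has 1 library. The Schwann and mesothelial comparisons rest on 307 and 533 cells.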

Other observations

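All tests below except the immediate early gene comparison, both comparisons with Schwann and mesothelial cells and the ratio of the lowest old to the highest young cluster were chosen after the results they bear on had been seen. Mesenchymal clusters led by the developmental transcription factor genes Tbx20 and Tcf21 appeared in both libraries, cluster 8 with 923 young cells and cluster 20 with 216 old cells. A subcluster of 41 young stromal cells was led by Col2a1, the cartilage collagen gene. The unnamed cluster 9, which both libraries shared, had little of the nuclear RNA Malat1, 1821.5 CPM in young and 2645.7 CPM in old cells against 26731 and 25708 CPM in fibroblastic stromal cells, and much S100a6, a calcium-binding protein gene, at 23621 and 26274 CPM against 6465 and 7952 CPM. Its Acta2 stood at 3444 and 5362 CPM and its Tagln at 2147 and 2484 CPM, which was not lower in the old library as in stromal cells. Gm42418, a noncoding gene that overlaps a ribosomal RNA repeat, was higher in the old library in each class compared, 7.01-fold in stromal, 4.37-fold in mesothelial and 8.18-fold in Schwann cells.

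The higher chemokine and cytokine levels of old stromal cells were set against digestion stress, free RNA and handling. Between 1814 old cells with the fewest and 2352 young cells with the most immediate early UMIs, the immediate early median was -0.93 while the chemokine median stayed at 3.33 (3.12 to 3.65), which argues against stress as read from these genes. Free RNA from macrophages or endothelial cells would bring their markers along, but chemokines exceeded the markers by 8.90 log2 units for endothelial cells and 12.1 for macrophages, comparing stromal with source CPM in the old library. Handling of the old library could still account for the pattern. The chemokine median was above 0 in all 3 classes compared (lowest 1.51, mesothelial), as it would be with age. Free RNA from old stromal cells would also raise chemokines in Schwann and mesothelial cells, and this source was not tested. Age and handling cannot be told apart with 1 library each, and age itself was not tested. A difference in the part of the aorta sampled, which is not given, was not tested either.

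The near-complete separation of young and old stromal cells into different clusters may reflect a shift of the whole library or a change in these cells. At equal cells and UMIs, the spread of log2(old/young) over genes in stromal cells was 1.45 times that in Schwann and 1.44 times that in mesothelial cells (medians of 100 draws, lowest draw 1.33), between the bounds set in advance. Across genes, which are not independent, the stromal ratios correlated with those in mesothelial cells at 0.653 and in Schwann cells at 0.439 after correction for counting error. The bounds set in advance asked for both values at 0.8 or more or both under 0.5, and only the Schwann value was under 0.5. Free RNA from stromal cells in Schwann and mesothelial cells could also raise these correlations, and this source was not tested. Neither test decides, so a shift common to the library and a change of stromal cells cannot be told apart, and both could contribute. Tissue from another part of the aorta, weighed below for the Hox genes, was not tested as a source of the separation.

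The Hox pattern could come from tissue taken at different positions along the aorta, from another mix of stromal cells, or from age. Log2(old/young) increased with paralogue group at a Spearman rho of 0.602 over 24 genes in stromal cells and 0.658 over 25 genes in other mesenchymal clusters. This rise restates the pattern, and among the 6 Hox genes outside the fixed list rho was 0.371 and 0.543, with Hoxc13 lower, so position and age cannot be told apart. For a different mix, the test written in advance compared the lowest old cluster (cluster 20, posterior to anterior UMI ratio 0.189) with the highest young one (cluster 0, 0.183) and gave 1.03, which decides nothing. A further test, chosen after that result, set the ratio over all old clusters (0.383) against the highest young cluster and gave 2.09. Any mix of whole young clusters would stay below that. The limit rests on 1 value per cluster, so a different mix of finer states within the young clusters was not excluded.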
